A study of Mus musculus with 2 samples.

How the data were processed

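The series holds 2 poly(A)-selected RNA-seq libraries of mouse embryonic cortex, 1 from WT and 1 from RBM3KO embryos. Per the labels, the mothers were made hypothermic at embryonic day 14, the cortex was taken at embryonic day 16, RNA was extracted with Trizol, enriched on oligo(dT) beads, fragmented, reverse transcribed with random primers and amplified by PCR. The genotype labels set the groups. The column names of the deposited table carry the number 2 after each genotype, which the labels lack, and columns were matched to libraries by genotype alone. The labels do not state how many embryos each library held.

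Per the submitters' processing notes, TopHat2 2.0.12, Bowtie 1.0.1 and HTSeq 0.6.0 were used with genome build mm10. The annotation version, the strand setting and the treatment of reads with several alignments are not given in the sources used here, so overlapping and antisense genes and genes with near-identical copies are uncertain. The deposited table gives for each Ensembl gene the raw read count of each library, per the file headers. It lists 21704 genes with annotations, and 1 line of it held no gene and was not analysed here. A gene at 0 counts in 1 library was listed with at least 5 counts in the other, while genes with 1 count in each library, such as Rhag, were listed. The authors' normalized values are CPM, which are counts scaled to the library total: count divided by value was constant within each library, and a count of 0 was given the value of 0.5 count. The authors' fold change is the ratio of the normalized values of RBM3KO over WT, and the authors' log2 fold change is its logarithm. The authors' p-value and adjusted p-value come from a test that the sources used here do not name.

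Counts were scaled with edgeR 4.0.16 (TMM) in R 4.3.3, and edgeR's quasi-likelihood test could not be fitted because 1 library per genotype leaves no residual degrees of freedom. The effective library size of RBM3KO was 0.949 of that of WT. The log2 ratio of RBM3KO over WT was taken after adding 0.5 count. A gene was measured when the mean normalized count of the 2 libraries was at least 20, which 14663 genes met. A gene was past the rule of size when it was measured, its absolute log2 ratio was at least 1 and its exact 95% conditional binomial (Clopper-Pearson) interval excluded a ratio of 1. Reads carry no molecular identifiers, so intervals and floors cover counting error only. Where 1 library had 0 counts, the fold was computed against a floor of 3 counts in that library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

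The main gene lists, comparisons, alternatives and the naming rule were fixed before the data were examined. Several tests, alternatives and lists described below were added afterwards. There were 33 lists of cell type markers and pathways, written from textbook knowledge. The position of a list was described as the percentile of its median log2 ratio among the medians of 10000 random lists of the same size, drawn from 50 bins of mean expression. The interval of a list's median came from 1000 resamplings of its members' counts. The text names Rbm3 and Yap1, the 10 genes with the highest and the 10 with the lowest log2 ratio among those past the rule with a mean normalized count of at least 50 (leaving out symbols of Gm with digits, Rik or pseudogene suffixes and names that look like clones), up to 4 members per list with the largest absolute log2 ratio plus any member past the rule, and the 5 most abundant genes of each library. From the named list members, those best covered by reads or best known are printed, and 1 gene that met the naming rule is not reported here. Genes within 1 Mb of Rbm3 were to be named if past the rule.

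Near-identical copies were sought with BLAST 2.17.0 (megablast) among GENCODE M21 transcripts of the listed genes. A copy needed at least 95% identity over at least 100 bases and 50% of the shorter transcript, at a place that did not overlap the gene. In GENCODE M21, 90.0% of the listed genes had identical positions. The search was first run on the longest transcript of each gene alone, which found a copy for 39 of the 199 genes past the rule and for 16 of the 26 with an absolute log2 ratio of at least 3. It was widened to all transcripts after Tpm3 and Tpm3-rs7 were seen to be missed, which raised these numbers to 51 and 25. The trend of the log2 ratio over GC content and transcript length was removed by a cubic least-squares fit over measured genes, with log2 ratios held between -1 and 1 for the fit. That correction, the alternatives without copies, and lists of motile cilia genes and further choroid plexus genes were added after seeing the data.

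The scripts were tested on simulated counts for this comparison, drawn for the 21704 listed genes from the libraries' means and sizes, with 200 genes changed 1.5-fold or 3-fold. The 95% interval held the true ratio for 95.5% of measured genes. The rule recovered 99.0% of measured genes changed 3-fold and 3.03% of those changed 1.5-fold, and 18 of 14472 unchanged measured genes passed it. The simulated counts held Poisson counting error alone. These rates therefore leave out variation between animals and between library preparations, and are not error rates for the genotypes. The alternatives were DESeq2 1.42.0 size factors, total counts, total counts without globin and mitochondrially encoded genes, no filter, a minimum mean of 100, a pseudocount of 5, thresholds of 1.5-fold and 3-fold, no interval, an interval wholly beyond 2-fold, and the authors' normalized values on the log2(value + 1) scale. DESeq2 and edgeR supplied scaling factors only.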

Results

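RNA was sequenced from the cerebral cortex of mouse embryos at embryonic day 16, after the mothers had been made hypothermic at embryonic day 14. Cortex of wild-type embryos (WT) was compared with cortex of embryos lacking RBM3 (RBM3KO), on a background labelled C57 black. RBM3 is an RNA-binding protein whose synthesis increases when cells are mildly cooled. Each genotype was represented by 1 library, so the comparison asked how the cooled cortex differed between these 2 libraries, and no difference below has a replicate check. The RBM3KO library held 17835461 counts assigned to genes and the WT library held 18629292. The most abundant transcripts were the same in both, among them mt-Co1 with 159909 counts in RBM3KO and 164859 in WT, and the neuronal tubulin Tuba1a with 147867 and 140282. Tuba1a and mt-Co1 both have near-identical copies elsewhere in the genome, so their counts are uncertain.

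Rbm3, the targeted gene (ENSMUSG00000031167), lies on the minus strand of chromosome X at 8138975 to 8145880 in mm10. It had 999 counts in the RBM3KO library and 7723 in the WT library. After scaling, the RBM3KO library kept 13.6% of the WT level (95% counting interval 12.7% to 14.6%), a 7.33-fold lower level and a log2 ratio of -2.87 (-2.97 to -2.78). The direction was that of the labels, although reads remained. Of the 30 measured genes within 1 Mb of Rbm3, 0 were past the rule of size, and their log2 ratios lay between -0.19 and 0.51. Cirbp, the other well-known cold-inducible RNA-binding protein, had a log2 ratio of 0.21 (0.15 to 0.27). The list of cold-inducible genes had a median of 0.01 over 9 measured members, and Rbm3 alone among them was past the rule and drew their mean to -0.30. With the trend of the log2 ratio over GC content and transcript length removed, that median was -0.04 (percentile 3.29).

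Most genes stood at similar levels in both libraries. Of 14663 measured genes, 73 were higher and 126 lower in the RBM3KO library by at least 2-fold with a counting interval that excluded no difference. These 199 genes were 1.36% of those measured, and 93.3% of measured genes had a log2 ratio between -0.5 and 0.5. Among 13237 measured protein-coding genes, 43 were higher and 94 lower. The genes lower in RBM3KO included Rbm3 itself, choroid plexus genes and retrotransposed gene copies. The higher genes included the sarcomere genes Ttn and Myh6, while another sarcomere gene, Tmod4, named after its value was seen, was lower. The counts are descriptive, since 1 library per genotype allows no test across genes, and each interval covers counting error only and compares the libraries, not the genotypes.

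**Figure D1:**
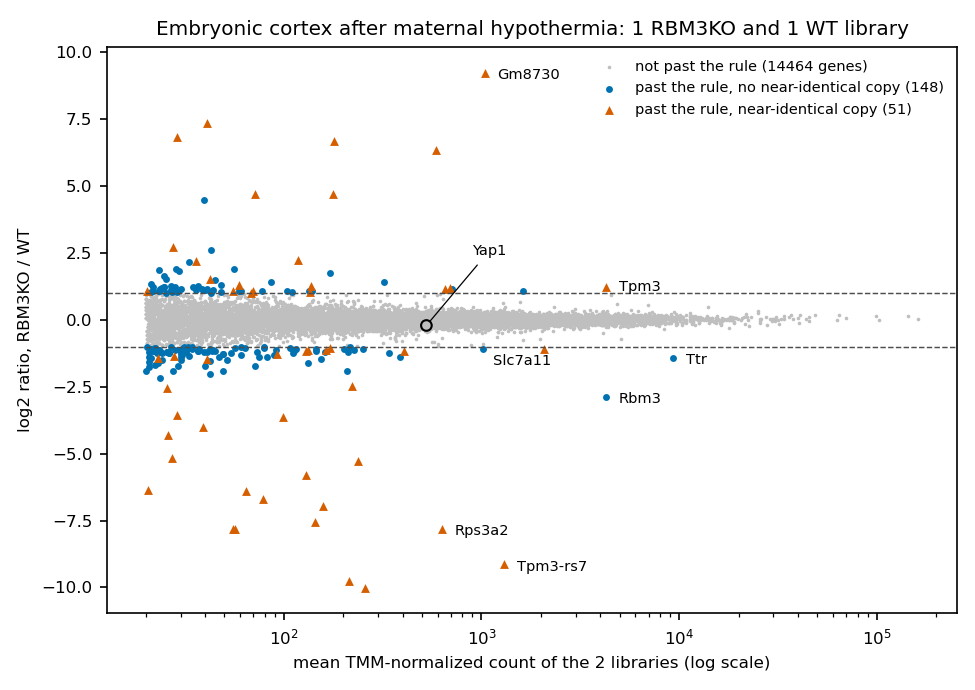
Log2 ratio of RBM3KO over WT against the mean TMM-normalized count of the 2 libraries (log scale) for 14663 measured genes. Grey points did not pass the rule of size, blue points passed it and have no near-identical copy, orange triangles passed it and have a copy (51 genes), and the dashed lines mark log2 ratios of -1 and 1. Rbm3 stood at -2.87, and Yap1 (ringed) at -0.21 lay among the genes near 0.

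Of the fixed lists, that of choroid plexus genes held the most genes lower in the RBM3KO library. The choroid plexus is the epithelium that secretes cerebrospinal fluid, and 9 of its 15 measured markers were at least 2-fold lower, 0 higher. Ttr, the thyroxine carrier transthyretin, had 4940 counts in RBM3KO and 13975 in WT, a log2 ratio of -1.42 (-1.47 to -1.38). Folr1, a folate receptor, stood at -1.47 (-1.86 to -1.10), Calml4 at -1.40 (-1.97 to -0.88) and the chloride channel protein Clic6 at -1.37 (-1.61 to -1.14). The water channel Aqp1, the potassium channel subunit Kcne2, the tight-junction gene Cldn2, the clotting factor F5 and the bicarbonate transporter Slc4a5 were also past the rule, with log2 ratios from -1.06 for Slc4a5 to -1.18 for Cldn2. The median of the list was -1.10 (-1.21 to -0.77), below that of each of 10000 random lists matched on expression. Prlr, at 0.35 (-0.49 to 1.22) on 28 and 23 counts, was the only measured member above 0 and is named after its value was seen.

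Markers of the tissue that covers the cortex were also lower in the RBM3KO library, by less. Of 13 measured markers of meninges and fibroblasts, 11 had log2 ratios below 0 and 0 were past the rule, with a median of -0.31 (-0.43 to -0.12) at percentile 0.05 of random lists. The collagen genes Col1a2 and Col3a1 stood at -0.70 (-1.01 to -0.40) and -0.54 (-0.90 to -0.18), and the small proteoglycan Ogn at -0.67 (-1.08 to -0.27). Markers of endothelium and pericytes had a median of -0.01 (percentile 38.2), with the endothelial claudin Cldn5 at 0.30 (0.13 to 0.46) and the vascular cadherin Cdh5 at -0.26 (-0.50 to -0.02). Markers of thalamus and diencephalon had a median of 0.01 (percentile 50.1) over 7 measured members. Both choroid plexus and meningeal lists kept their place after the trend of the log2 ratio with GC content and transcript length was removed, with medians of -1.07 and -0.36.

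Genes of cells from the ventral forebrain stood slightly higher in the RBM3KO library. Markers of GABAergic interneurons, which migrate into the cortex from the ganglionic eminences, had a median log2 ratio of 0.17 (0.10 to 0.21), above that of each of 10000 random lists, and 15 of 19 measured members were above 0. The neuropeptide genes Npy and Sst stood at 0.44 (0.28 to 0.60) and 0.35 (0.25 to 0.46), and the homeobox genes Dlx5 and Dlx2 at 0.36 (0.22 to 0.50) and 0.31 (0.22 to 0.41). Not all members went this way: among genes named after their values were seen, Dlx6os1, an antisense transcript and so uncertain, stood at -0.29 (-0.39 to -0.18) and Erbb4 at -0.17 (-0.28 to -0.07), and Gad1 and Gad2, which encode the enzymes that make GABA, at 0.06 and 0.01. Markers of ganglionic eminence and striatum had a median of 0.12 (0.05 to 0.20) at percentile 99.3, with the adenosine receptor gene Adora2a at 0.49 (0.26 to 0.73) and the enkephalin gene Penk at 0.49 (0.15 to 0.84), while Gsx2 was at -0.47 (-0.95 to -0.00). Of the members of these 2 lists, 0 reached a 2-fold difference. With the GC and length trend removed, the medians were 0.12 and 0.20, both at percentile 100.

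Of the markers of neural progenitors and excitatory neurons of the cortex, 0 were past the rule. The median log2 ratio was -0.01 for 22 radial glia markers (percentile 23.5), with the homeobox gene Emx2 at 0.26 (0.11 to 0.41) and the repressor Gli3 at -0.25 (-0.40 to -0.10). It was -0.01 for 15 intermediate progenitor markers (percentile 45.5), 0.06 for 15 deep-layer neuron markers (percentile 89.7) and 0.03 for 15 upper-layer neuron markers (percentile 71.1). The deep-layer gene Rprm stood at 0.29 (0.21 to 0.37) and Sox5 at -0.17 (-0.24 to -0.10). Pan-neuronal genes had a median of 0.04 (percentile 72.7), with the microtubule gene Dcx at -0.18 (-0.20 to -0.15) and the tubulin Tubb3 at 0.17 (0.15 to 0.19). Cajal-Retzius markers had a median of -0.08 (-0.12 to 0.04) at percentile 7.46, and synaptic genes had a median of 0.01 (percentile 57.5), with the calcium channel gene Cacna1e at -0.33 (-0.40 to -0.25). With the GC and length trend removed, the medians were 0.07 for synaptic genes (percentile 99.475), 0.07 for upper-layer neurons (percentile 98.4), 0.06 for pan-neuronal genes (percentile 98.1) and 0.05 for deep-layer neurons (percentile 91.3). They were -0.05 for intermediate progenitors (percentile 3.81), 0.02 for radial glia (percentile 64.6) and 0.03 for Cajal-Retzius cells (percentile 64.2), and the last 2 thus changed sign.

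Among glial and blood lineages, 2 genes were past the rule, and the erythroid list stood high among random lists. Fcrls, a microglial receptor-like gene, was higher in RBM3KO with 123 against 48 counts and a log2 ratio of 1.42 (0.94 to 1.95), whereas the 17 measured microglial and macrophage markers had a median of -0.05 (-0.22 to 0.12) and Fcer1g stood at -0.95 (-1.86 to -0.12). Tspo2, an erythroid gene, was higher at 1.23 (0.34 to 2.24) on 34 and 15 counts, and the 6 measured erythroid genes had a median of 0.24 (0.15 to 0.29, percentile 99.7), which became 0.10 (percentile 91.3) with the GC and length trend removed. The globin genes Hba-a1 and Hba-a2, near-identical to each other and therefore uncertain, stood at 0.27 and 0.21. Markers of oligodendrocyte precursors and astrocytes had a median of 0.11 (-0.04 to 0.15, percentile 97.3), with Olig1 at 0.28 (0.11 to 0.46) and the growth factor receptor Pdgfra at -0.29 (-0.50 to -0.09), and that median became 0.05 (percentile 82.5) with the trend removed. Xist, which female cells express and which is named here as a check of sex after its value was seen, had 5 counts in RBM3KO and 4 in WT, while Y-linked genes were abundant in both, with Eif2s3y at 1331 and 1614 counts. The 4 measured Y-linked genes had a median of -0.18 (-0.25 to -0.08), or -0.10 with the trend removed.

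Yap1, which encodes the transcriptional effector of the Hippo pathway and was chosen beforehand, had 476 counts in RBM3KO and 579 in WT. Its log2 ratio was -0.21 (-0.39 to -0.03), short of the 2-fold rule, and 15.9% of the 1000 genes nearest to it in expression differed by at least as much. Of 22 measured Hippo pathway components 0 were past the rule, and their median was -0.07 (-0.12 to -0.01) at percentile 1.01, or -0.03 at percentile 5.09 with the GC and length trend removed. The scaffold gene Wwc2 stood at -0.30 (-0.50 to -0.10), the kinase gene Lats1 at -0.18 (-0.28 to -0.09) and its partner Mob1b at -0.19 (-0.32 to -0.07). The 21 measured target genes of YAP had a median of 0.00 (-0.08 to 0.08, percentile 43.0), with 0 past the rule. Among them Ptpn14 stood at -0.95 (-1.45 to -0.46) and Dock5 at -0.82 (-1.43 to -0.25), while Cyr61 stood at 0.41 (0.15 to 0.66) and Ctgf, part of whose exons overlaps another gene, at -0.26 (-0.74 to 0.21). Neither Yap1 nor the median of its targets stood outside the spread of similarly expressed genes or of random lists in these 2 libraries.

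Genes of the cell cycle stood slightly lower in RBM3KO. Of 36 measured S-phase and mitotic genes 27 were below 0, 0 were past the rule, and the median was -0.07 (-0.13 to -0.04) at percentile 0.42, or -0.04 at percentile 0.87 without the GC and length trend. The spindle checkpoint kinase gene Bub1b stood at -0.44 (-0.59 to -0.29), the mitotic motor Kif11 at -0.38 (-0.52 to -0.25) and the proliferation marker Mki67 at -0.32 (-0.40 to -0.24), whereas the S-phase regulator E2f1 was at 0.33 (0.12 to 0.54). Axon guidance and adhesion genes had a median of -0.06 (-0.10 to -0.03) at percentile 0.54, led by the netrin receptor Dcc at -0.43 (-0.60 to -0.26) and Cntn1 at -0.26 (-0.37 to -0.14). That median became -0.00 at percentile 15.2 once the GC and length trend was removed. Wnt target genes had a median of 0.02 (percentile 58.5), with Wnt8b, a gene of the cortical hem, at -0.75 (-1.31 to -0.22). Notch pathway genes had a median of 0.04 (percentile 76.9), and Nrarp, whose exons largely overlap another gene, stood at 0.55 (0.09 to 1.02). The median of the Notch pathway became -0.01 (percentile 36.3) with that trend removed.

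Stress pathways showed 1 gene past the rule. Slc7a11, the cystine transporter that feeds glutathione synthesis, was lower in RBM3KO with 639 against 1412 counts, a log2 ratio of -1.07 (-1.21 to -0.93). With the GC and length trend removed Slc7a11 stood at -0.95, inside that interval but short of 2-fold. The other 21 measured genes of the unfolded protein and integrated stress response were not past the rule, and the median of the list was -0.02 (percentile 27.8), or -0.04 (percentile 4.76) with the trend removed. Heat shock genes had a median of -0.01 (percentile 27.9), with the constitutive chaperone gene Hspa8 at 0.32 (0.30 to 0.35) and the heat shock factor Hsf1 at 0.23 (0.10 to 0.35), and 0.00 (percentile 31.9) with the trend removed. Hypoxia and glycolysis genes had a median of 0.04 (percentile 74.9), with Pdk1 at -0.27 (-0.43 to -0.10), and -0.01 (percentile 18.98) with the trend removed. For p53 response genes the median was -0.04 (percentile 10.5, or 4.39 with the trend removed), with the pro-apoptotic Pmaip1 at -0.84 (-1.54 to -0.19), and for interferon-stimulated genes it was 0.08 (-0.13 to 0.23, percentile 74.3).

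Immediate early genes, which neurons induce on activity, had a median log2 ratio of 0.21 (0.05 to 0.25) at percentile 99.97. Nr4a1 stood at 0.58 (0.27 to 0.89) and Npas4 at 0.37 (0.05 to 0.69), and 0 of 16 measured members were past the rule. Nuclear genes of the respiratory chain had a median of 0.11 (0.06 to 0.13) at percentile 99.98, with 24 of 28 above 0 and Cox6a1 at 0.31 (0.23 to 0.38). Ribosomal protein genes had a median of 0.09 (0.08 to 0.10), above that of each of 10000 random lists, with 75 of 78 above 0, but 58 of the 78 have near-identical copies and are uncertain. With the GC and length trend removed the medians were 0.10 for immediate early genes (percentile 96.6), 0.06 for the respiratory chain (percentile 99.1) and 0.03 for ribosomal proteins (percentile 86.2). Mitochondrially encoded genes had a median of 0.00 (percentile 34.7). The trend itself ran across 14637 genes, with a Spearman rho of 0.31 between log2 ratio and GC content and -0.25 between log2 ratio and transcript length, over genes that are not independent replicates.

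**Figure D2:**
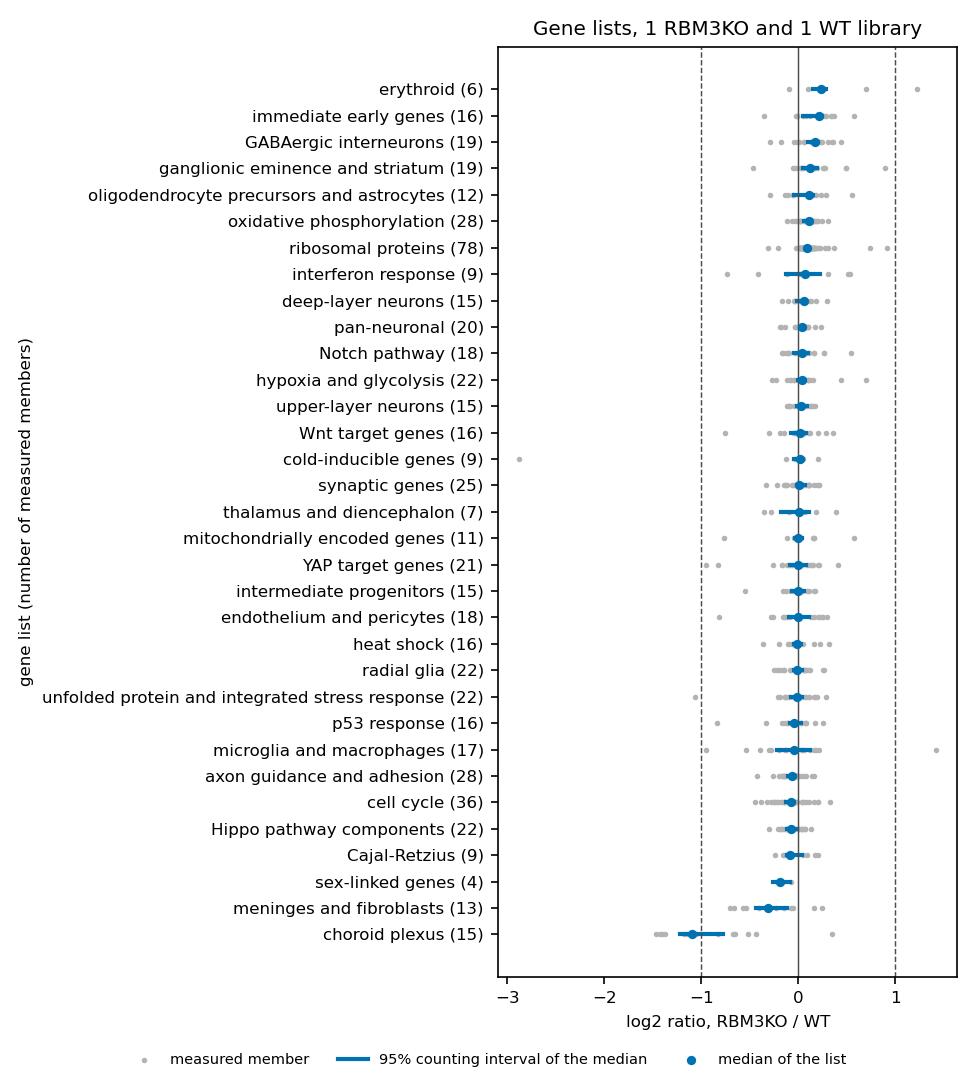
Log2 ratio of RBM3KO over WT for 33 gene lists, with the number of measured members in brackets. Grey points are measured members, blue points the median of each list, blue bars its 95% counting interval, and dashed lines log2 ratios of -1 and 1. The choroid plexus list, with a median of -1.10, stood apart from the others, whose medians lay between -0.31 and 0.24.

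Outside the lists, the genes named by size came from several functions. Those higher in RBM3KO included Ttn, the giant sarcomere protein titin, with 86 against 24 counts and a log2 ratio of 1.89 (1.25 to 2.63), and the cardiac myosin gene Myh6 at 1.08 (0.50 to 1.71), which has a near-identical copy. S100a10, an annexin partner, had 456 and 181 counts and a log2 ratio of 1.41 (1.16 to 1.66), and Shisa4 had 959 and 450 counts and 1.17 (1.00 to 1.33). The nicotinic receptor subunit gene Chrna3, the ethanolamine kinase gene Etnk2 and Lor, which encodes the epidermal protein loricrin, each stood at 1.08 on between 39 and 103 counts. With the GC and length trend removed Chrna3 stood at 1.13 and Etnk2 at 1.05, whereas Lor stood at 0.84, short of 2-fold. Those lower in RBM3KO included Wfikkn2, which encodes a secreted growth factor-binding protein, with 85 against 338 counts and -1.91 (-2.28 to -1.57), Aebp1 at -1.60 (-2.04 to -1.20) and the ciliary gene Cfap126 at -1.51 (-2.23 to -0.87). Some of the higher genes without a copy lay within 2 Mb of each other: Etnk2, Shisa4 and, named after its value was seen, Ube2t at 1.03 (0.62 to 1.46) on chromosome 1, and Lor and S100a10 on chromosome 3. The antisense genes Gm15445, Gm26781 and Gm26642, within 2 Mb of Shisa4, were also higher, at 2.17, 1.49 and 1.32. Being antisense, they are uncertain, and they are named after their values were seen. On the same stretch of chromosome 1 the gene Gm37333, also named after its value was seen, was lower with 8 and 40 counts.

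Gene copies gave the most extreme ratios. Of the 26 genes past the rule with an absolute log2 ratio of at least 3, 25 have a near-identical copy, against 5.92% of measured genes. Tpm3-rs7, a retrotransposed copy of the tropomyosin gene Tpm3 on chromosome 14, had 4 counts in RBM3KO and 2665 in WT, while Tpm3 itself had 5836 and 2637, a log2 ratio of 1.22 (1.15 to 1.29). Rps3a2 had 5 and 1293 counts, and its parent Rps3a1 had 10126 and 8608. In the other direction, Gm8730, a pseudogene of the ribosomal protein gene Rplp0, had 2019 counts in RBM3KO and 3 in WT, while Rplp0 had 15658 and 20419. Gm6166 and Gm9825 had 0 counts in RBM3KO and 528 and 440 in WT, at least 167-fold and at least 139-fold lower against a floor of 3 counts. The enolase copy Eno1b had 937 and 432 counts, against 4814 and 5921 for Eno1. Tpm3-rs7, Rps3a2, Rps3a1, Eno1b, Eno1 and Tpm3 fell under the naming rule, and the other copies and partners here were chosen after their values were seen. All of these values are uncertain, because reads that fit a copy and its parent equally can be assigned to either.

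In the authors' deposited table, 821 genes had a p-value below 0.05 and an absolute log2 fold change above 1, with 354 higher and 467 lower in RBM3KO. All 199 genes past the rule of size were among the 821 in the authors' deposited table. The authors' deposited table marks 334 genes as significant, 135 higher and 199 lower, which are the genes with an adjusted p-value below 0.05 and an absolute log2 fold change above 1, and 182 of them were past the rule of size. Of the 334 genes marked in the authors' deposited table, 150 had a mean normalized count below 20. For Rbm3 the authors' deposited table gives a log2 fold change of -2.89. For Yap1 the authors' deposited table gives a log2 fold change of -0.22, a p-value of 0.0136 and an adjusted p-value of 0.0775. These p-values come from 1 library per genotype and cannot reflect variation between animals.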

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

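The alternatives without copies, for protein-coding genes alone and with the GC and length trend removed were chosen after seeing the data. No paired analysis was possible because each genotype has 1 library, and no library could be left out for the same reason. The numbers of genes higher in RBM3KO (73) and genes lower in RBM3KO (126) stayed within 1.5 times under the other scalings (71 to 72 higher, 132 lower), with a pseudocount of 5, without an interval, without copies (52 and 96), without copies and choroid plexus lists (52 and 87) and with the trend removed (67 and 128, of which 63 and 118 were the same genes). They became 246 higher and 330 lower with no filter, 18 and 35 with a minimum mean of 100, 208 and 305 at 1.5-fold, 19 and 34 at 3-fold, 20 and 31 with the whole interval beyond 2-fold, and 27 and 52 on the authors' normalized values, where adding 1 CPM shrinks the ratios of genes with few reads. Taking out the choroid plexus lists could only remove the 9 markers of the fixed list that were past the rule, because the further list left out genes already called. That alternative does not show how many of the remaining 87 lower genes depend on choroid plexus tissue. Among protein-coding genes 43 were higher. An adjusted p-value took the authors' calls from 821 to 334. Rbm3 and Yap1 kept their direction and stayed inside their counting intervals under every alternative run. No list median or named gene with an interval excluding 0 changed sign.

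List medians outside their counting interval were few. With DESeq2 size factors the pan-neuronal median log2 ratio was 0.0206 and the ribosomal proteins median log2 ratio 0.0715, and with total counts alone the latter was 0.0782. With no filter, thalamus and diencephalon stood at 0.37 and erythroid genes at 0.10, as members with few reads entered. On the authors' normalized values choroid plexus was -0.75 and ribosomal proteins 0.0780. Without copies the erythroid median was 0.40. With the trend removed, ganglionic eminence and striatum stood at 0.20, erythroid genes at 0.10, cell cycle at -0.0413, hypoxia and glycolysis at -0.00558, ribosomal proteins at 0.0292 and axon guidance and adhesion at -0.00404. The cause was not tested for the lists moved by scaling. The alternatives planned for RPKM values did not apply, because the deposited table holds counts.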

Other observations

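The tests of read placement between copies, of a processing step favouring 1 library, of genes past the rule lying together, of other neighbouring tissue and of the reads left at Rbm3, and the motile cilia list, were chosen only after the results were seen. Further genes past the rule, outside the naming rule, are named here after their values were seen. Of 1733 terms of biological process examined, 18 pairs of term and direction held at least 3 genes past the rule, and the terms given here were picked from these after they were seen. The carbonic anhydrase genes Car12 and Car14 were lower in RBM3KO at -1.25 (-1.50 to -1.01) and -1.31 (-1.81 to -0.83). With Slc4a5, a choroid plexus marker already counted above, they made 3 lower genes among the 15 measured members of the term regulation of pH. That number was reached by 0.01% of matched random lists, the smallest share these could give. The term positive regulation of lamellipodium assembly, with Aqp1, Gm8822 and Rac2 lower, had the same share. Of these, Aqp1 is a choroid plexus marker already counted above. Gm8822 is a pseudogene with a near-identical copy, at 0 counts in RBM3KO and 116 in WT, so its value is uncertain. The median of the 12 measured members of that term was 0.01 (percentile 45.6), so the term as a whole was not lower. Ciliary genes were picked by eye among those past the rule, which tests nothing about ciliary genes as a group: lower were Cfap54, Cfap61, Cfap65, Cfap70, Cfap126, Ak7, Daw1, Dnah8, Dnali1, Gmnc, Lrriq1, Pifo and Ttc21a, with log2 ratios from -1.01 for Cfap65 to -1.71 for Dnah8, while the ciliary kinesin gene Kif19a was higher at 1.01 (0.35 to 1.72). A list of 34 motile cilia genes that left out those already seen had a median of -0.16 (-0.29 to -0.04) at percentile 2.67 over 25 measured members, a median that leaving them out draws toward 0, with Dnah6 at -0.83 (-1.28 to -0.41) and the master regulator Foxj1 at -0.10 (-0.35 to 0.14).

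Of the clustered protocadherin genes, which encode variable cell-surface labels of single neurons, 5 were lower past the rule, and others went the other way. Pcdhb5 stood at -1.39 (-2.13 to -0.73), Pcdhgb5 at -1.30 (-1.93 to -0.73), Pcdhgb6 at -1.19 (-1.51 to -0.89), Pcdhga11 at -1.11 (-1.60 to -0.65) and Pcdhga3 at -1.08 (-1.46 to -0.72), while Pcdhb11 stood at 0.82 (0.41 to 1.25) and Pcdhb7 at 0.74 (0.47 to 1.02). The gamma genes share exons, so their counts are uncertain and not independent. The term for homophilic adhesion held 7 lower genes among 137 measured, but 4 of them are these gamma genes, so no comparison with random lists is given, and its median was -0.03. Of 28 measured members of the term muscle contraction, Ttn, Myom1 and Myh6 were higher, a number reached by 0.06% of random lists. The median of the term was 0.05 at percentile 84.9. The muscle genes Tmod4 and Perm1 went the other way, at -1.90 (-2.71 to -1.20) and -1.22 (-1.66 to -0.80). Capn11, with 74 counts in RBM3KO and 3 in WT and a log2 ratio of 4.48 (3.10 to 7.01), was the gene with an absolute log2 ratio of at least 3 for which no copy was found.

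The on or off behaviour of gene copies was weighed first. Of 14 pairs in which the shift could be resolved, the partner moved the other way in 9 (64.3%), which left open whether reads moved between copies. The split by position, made after seeing the pairs, gave 9 of 9 (100%) where the partner lay on another chromosome. It gave 0 of 5 (0%) where the partner lay on the same chromosome. Moving reads may account for the first kind, but direction alone cannot decide it. Most of these copies were lower in RBM3KO, so any partner above 0 counted as moving the other way. Several partners are ribosomal protein genes, of which 75 of 78 were above 0. The shifts in normalized counts often differed in size: 2764 for Rps18 against -250 for its copy AL607105.1, and 1374 for Rpl15 against -313 for Gm10020. They were closer for Tpm3 (3421) and Tpm3-rs7 (-2592). For the second kind moving reads were argued against only for the best-expressed partner, since no other was examined. Among those pairs 5830417I10Rik and 1500004A13Rik overlap and share the partner Gon4l, so they are not independent. The partners Xlr4c and Gm13212 had few counts. Since 7 copies stood higher in RBM3KO beside 18 higher in WT, a processing step raising every copy in the same library was argued against. A step that favours most copies in WT stayed open, because it could give such numbers too. Stretches of the genome that differ between the libraries, such as strain segments around a targeted allele, were weighed last. The outcome set beforehand against them was that small-shift genes lie near genes past the rule no more often than in the median relabelling. Of 585 such genes, 195 lay within 2 Mb, where the median of matched relabellings was 200 (percentile 31.2). By that outcome this argued against such stretches, but only weakly, since 195 was well inside the spread of relabellings. Of 148 genes past the rule without a copy, 35 had another of the same direction within 2 Mb. That number, at percentile 86.6 where the median relabelling gave 28, did not decide, so such stretches were not excluded.

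The lower choroid plexus genes may reflect how much of that tissue was dissected with the cortex, or a biological effect of the genotype, which was not tested. A smaller share of choroid plexus tissue predicted that further genes of this tissue would be lower too, with a size of the median and a share below 0 set beforehand. A list of 20 measured genes had a median of -0.31 (-0.41 to -0.18), short of the predicted size. Of its members, 17 (85%) were below 0, which met the predicted share. That list left out genes already called, which draws its median toward 0, so it cannot decide and this stays open, and Ttr at 4940 and 13975 counts was the most abundant gene concerned. None of the 16 listed choroid plexus markers belongs to another list, but how many the cortex itself expresses was not determined. A smaller share of all neighbouring tissue alike was argued against, since the ganglionic eminence list stood at 0.12, 0.89 above the upper end of the choroid plexus interval. The meninges and fibroblasts list was lower at -0.31 (percentile 0.05), so a smaller share of choroid plexus and meninges together was not argued against.

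The Rbm3 reads left in the RBM3KO library may come from a transcript of the altered allele, which counts per gene cannot show, or from tissue with an intact gene. Tissue of heterozygous females was argued against by 5 Xist counts in RBM3KO. Tissue like that of the WT library would keep every abundant gene at 13.6% of its WT level or more, and 12 genes with at least 100 WT counts kept less, but all 12 have near-identical copies and 0 do not. Since reads of such genes can be placed differently in each library, this does not decide the matter, and the possibility stays open.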
